A study of Mus musculus with 6 samples.

How the data were processed

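RNA was sequenced from the aortas of C57BL/6 mice that were 15 weeks old and had been kept on a normal diet for 7 weeks from the age of 8 weeks. There were 3 libraries from wild-type mice and 3 from mice heterozygous for Palmd. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, mRNA was selected on poly-T beads, fragmented and primed with random hexamers, and the libraries were amplified by PCR. The kit named there is not described as keeping strand, so genes that overlap on opposite strands cannot be told apart. Neither the labels nor the files say whether each library came from a separate animal, so the p-values below measure the spread between these samples.

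The deposited files hold FPKM-type values, that is reads scaled by gene length and by the reads of the library, calculated by the authors, with 29752 genes in each file and a gene symbol beside each Ensembl identifier. Whether single reads or fragments were counted (RPKM or FPKM) is not stated, and the unit is written FPKM here. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3, TopHat2 and the build GRCm38, without saying which was used for which step. The counting tool and the annotation are not given in the sources used here. The unit was read from the values. Each value multiplied by the exon-union length of its gene in GENCODE release M21 (GRCm38) was a whole multiple of a fixed step in each library, within a tolerance of 0.01 reads, for 91.9% to 92.0% of the genes with few reads. Of the 29752 identifiers, 29687 were found in that annotation. The step gives the number of reads by which the authors divided, 17283951 to 18372130 per library, so that 1 read on a gene of 2 kb is worth 0.0272 to 0.0289 FPKM. No 2 libraries held the same values. The column headers inside the files number the heterozygote libraries differently from the titles (title number 1 has header number 3, title number 2 has header number 1, and title number 3 has header number 2). The titles were used throughout. The group is the same under both.

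A count model had been planned before the data were examined. Because the files hold a normalized unit, the planned replacement was used: limma with a mean-variance trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), heterozygote minus wild type, with all 6 libraries and no covariate, and no scaling beyond the authors' own. Genes with at least 1 FPKM in at least 3 libraries were tested (12620 genes), and 2620 genes were at 0 in all libraries. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of genes with low values. Levels are given as the mean ± SD of 3 libraries. Single values were also compared by an exact two-sided permutation test, which with 3 libraries against 3 cannot give a p below 0.1. Values were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plotted with matplotlib 3.10.9.

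Gene lists of programs, cell types, and RNA quality and handling (52 in all, including 1 of sex-linked genes that was kept for description) were fixed before the data were examined. Of their entries, 874 matched a symbol in the files, 9 of them through a RefSeq synonym, and 4 did not. The 47 lists with at least 3 tested members were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, and adjusted over the 47 lists. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the genes of a list move, on balance, in a given direction, without comparing them with other genes. List members were also counted after adjustment over the list alone.

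The rule for naming genes was fixed before the data were examined. It takes Palmd in every library, the 12 genes with the largest fold in each direction among those past the threshold or, where none passes, the 12 genes with the smallest p in each direction, given as values that did not pass. It leaves out predicted genes, pseudogenes and sex-linked genes and needs a mean of at least 1 FPKM, in place of the same number in CPM. For each list described it takes up to 4 members with the smallest p, and up to 6 for matrix, contractile and osteochondrogenic lists. The 10 genes with the highest mean are named once. Genes named outside this rule are said to be chosen after their values were seen.

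The procedure was tested on simulated values for the 12620 genes with the spread of these libraries. In 5 runs with 200 changed genes each, 58.2% of the genes changed by a fold of 2 and 87.2% of those changed by a fold of 4 were recovered, with 8 false calls per run. In runs with no change, 0.2 genes and 0.2 lists were called on average. Genes were drawn independently of each other there, so the simulation does not carry the correlation between genes and does not check the list calls for it. Its recovery rates may not hold for libraries with such correlation, so the absence of genes past the threshold does not exclude large changes. Nr1d1, for example, was at 6.19 FPKM in wild type and 67.9 FPKM in heterozygotes and did not pass.

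Alternatives fixed before the data were examined were limma voom on the recovered reads (11021 genes, tested among those whose reads came out whole in every library, with trimmed-mean scaling), median-of-ratios and upper-quartile scaling, no filter on low values, leaving out mitochondrially encoded and haemoglobin genes, leaving out striated muscle and adipocyte genes, a replicate block by title number, leaving out each library in turn, and other thresholds. Added after the data were seen were a block by header number, trimmed-mean scaling, pseudocounts of 0.1 and 0.5, a minimum of 5 FPKM, array quality weights, and the mean level of the white adipocyte markers as a covariate. Every file and every library was used.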

Results

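Transcripts were compared between 3 aortic libraries of wild-type mice and 3 of Palmd heterozygous mice. Palmd encodes palmdelphin, a protein of the paralemmin family. The libraries were of nearly equal depth. The number of reads behind the values was 18275767, 18372130 and 18009030 in wild type replicates 1 to 3 and 18260088, 17283951 and 18263324 in heterozygote replicates 1 to 3. Between 21484 and 22565 genes had a value above 0. The 10 genes with the highest mean were the mitochondrially encoded mt-Co1, mt-Cytb, mt-Nd1, mt-Nd2, mt-Nd5 and mt-Nd4, the smooth muscle actin Acta2, the ferritin chain Fth1, the matrix protein Sparc and the myosin light chain Myl9. Xist was at or below 0.0275 FPKM and Ddx3y between 16.7 and 21.6 FPKM in all 6 libraries, as in male tissue.

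Palmd itself (ENSMUSG00000033377, GRCm38 chromosome 3, 116918258 to 116968987) was at 5.49, 7.88 and 10.1 FPKM in wild type replicates 1 to 3 and at 5.31, 7.19 and 6.21 FPKM in heterozygote replicates 1 to 3. The means were 7.82 ± 2.30 and 6.24 ± 0.942 FPKM (SD, n = 3), so that the heterozygotes had 79.7% of the wild-type mean. The groups overlapped. The log2 fold change was -0.26 (SE 0.21, 95% interval -0.77 to 0.25, limma adjusted p = 0.915), and the exact two-sided permutation p was 0.4, where 0.1 is the smallest possible. The interval spans folds from 0.587 to 1.19. The labels do not say which part of the gene was altered, and reads over the whole gene may come from an altered allele as well, so the Palmd level does not check the genotype labels of these libraries. Its relative Palm was at 24.6 ± 3.15 FPKM in wild type and 25.2 ± 1.29 FPKM in heterozygotes, and Palm2 and Palm3 were at or below 0.368 FPKM in every library. Of 9 tested neighbours of Palmd on the chromosome, the member with the smallest p was Slc35a3 (log2 fold change -0.28, limma adjusted p = 0.744). The neighbours as a list were not called (mean log2 fold change -0.07, camera adjusted p = 0.398).

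**Figure D1:**
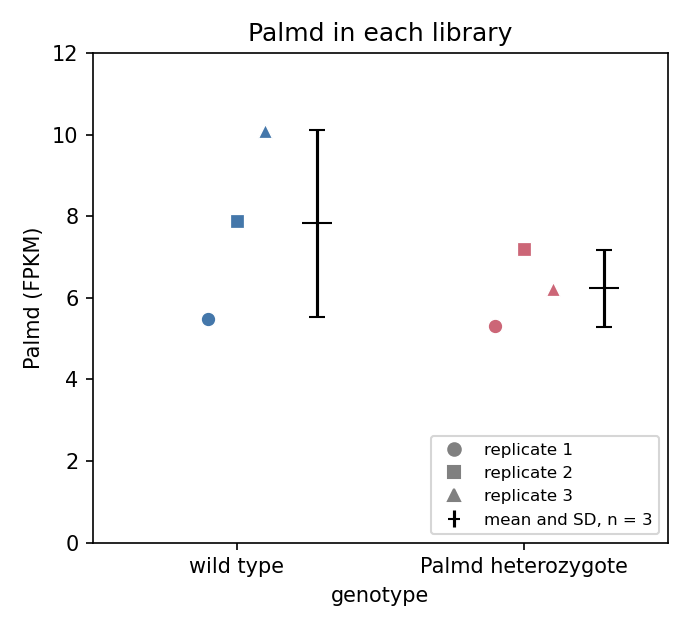
Palmd in FPKM (vertical axis) in each library of both genotypes, with the mean and SD of 3 libraries beside the points. The heterozygote values of 5.31 to 7.19 FPKM lie within the wild-type range of 5.49 to 10.1 FPKM or just below it.

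No gene passed the threshold in either direction. Among 12620 genes tested with limma, 0 had an adjusted p under 0.05 and the smallest adjusted p was 0.231. At an unadjusted p under 0.05 there were 820 genes, 512 higher and 308 lower in heterozygotes, where 631 are expected by chance. With limma voom on the recovered reads 0 genes passed and 779 had an unadjusted p under 0.05. The libraries of the groups did not overlap for 12.9% of the genes, 984 higher and 646 lower, where 10% are expected by chance. Heterozygote replicate 2 stood apart from the other libraries. Its mean correlation with them was 0.930, against 0.960 to 0.971 for the rest. Without it 0 genes passed, and 1762 had an unadjusted p under 0.05. That number was 451 without wild type replicate 2 and 432 without wild type replicate 3.

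None of the genes closest to the threshold passed it in the planned comparison of all 6 libraries. All 24 genes named by the rule passed with array quality weights and 14 with the adipocyte covariate. Both settings were chosen after the data were seen and are described below with their limits. Col6a6, a collagen VI chain (chromosome 9, 105687809 to 105828160), was at 2.75 ± 0.237 FPKM in wild type and 6.55 ± 0.397 FPKM in heterozygotes (log2 fold change 1.01, SE 0.10, limma adjusted p = 0.231). The carboxypeptidase Cpz was at 11.5 ± 1.90 and 25.5 ± 3.64 FPKM, the microfibril protein Mfap2 at 14.2 ± 1.46 and 29.0 ± 4.50 FPKM, and the gelatinase Mmp9 at 3.04 ± 0.365 and 5.67 ± 0.709 FPKM. Epm2a, which encodes the glycogen phosphatase laforin, had a log2 fold change of 0.74 (SE 0.09), and the kinase subunit Camk2b one of 0.97 (SE 0.12). Sec16b, Unc119, Pigz and Ky had log2 fold changes of 0.67, 0.52, 0.57 and 0.71. DQ267102 had one of 2.06 (SE 0.34). It is annotated as a small nucleolar RNA, a class with near-identical copies and poor capture by poly(A) selection, and its value is uncertain.

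On the lower side Smad6, an inhibitor of BMP signalling (chromosome 9, 63953076 to 64022059), was at 28.0 ± 1.98 FPKM in wild type and 13.4 ± 3.25 FPKM in heterozygotes (log2 fold change -1.03, SE 0.17, limma adjusted p = 0.459). The phosphatase Mtmr4 was at 12.1 ± 0.659 and 7.42 ± 0.212 FPKM, Nbeal2 at 8.83 ± 0.961 and 4.75 ± 0.294 FPKM, and the kinesin Kif26a at 14.7 ± 1.60 and 7.78 ± 1.09 FPKM. The transcription factor Tead4 and the GATA cofactor Zfpm1 had log2 fold changes of -0.81 (SE 0.15) and -0.77 (SE 0.13). Osgin1, Sema7a, Irf2bpl, Clic5 and Gpr4 had log2 fold changes of -0.91, -0.66, -0.62, -0.70 and -0.55. For each of these 24 genes all 3 heterozygote values lay on the same side of all 3 wild-type values, and the limma adjusted p ranged from 0.231 to 0.548. Choice by the smallest p favours such separation, which 12.9% of all tested genes showed.

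**Figure D2:**
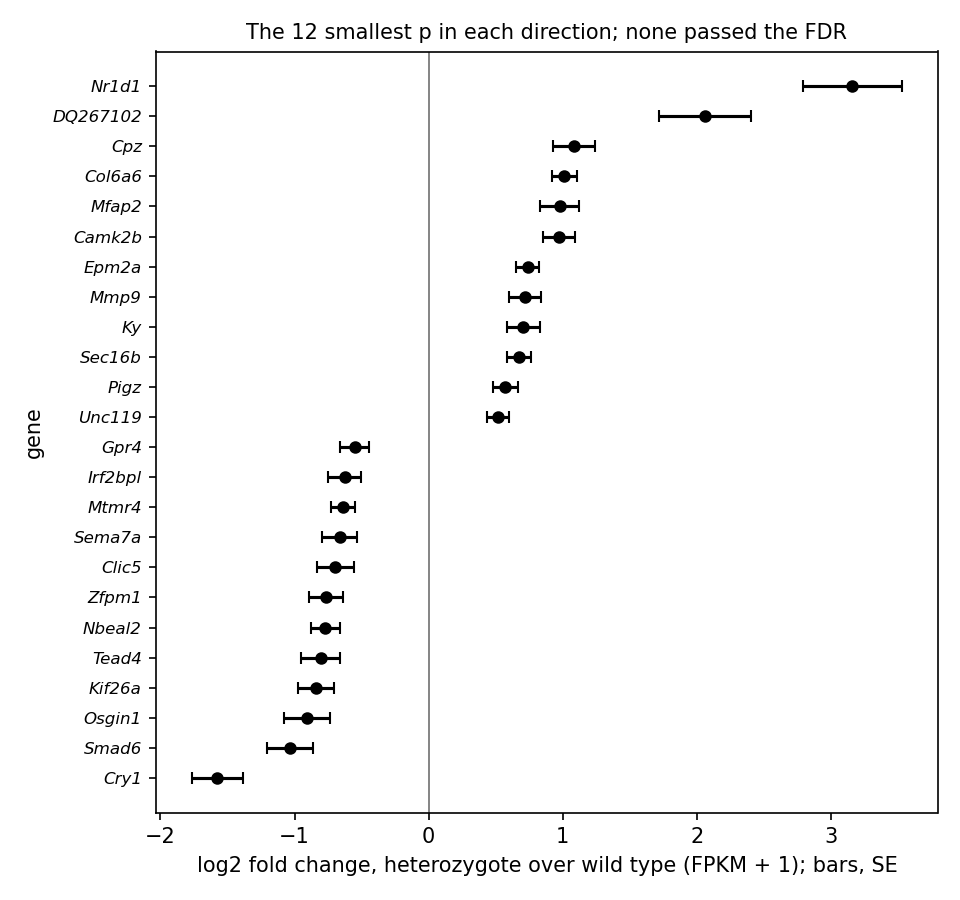
Log2 fold change of FPKM + 1, heterozygote over wild type (horizontal axis), of the 12 genes with the smallest p in each direction, with bars of 1 SE. They run from -1.58 for Cry1 to 3.16 for Nr1d1, and none passed the threshold.

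Among the 19 clock genes, 4 had all heterozygote values above and 2 all below the wild-type values. Nr1d1, the repressor REV-ERB alpha (chromosome 11, 98767932 to 98775333), was at 5.07, 5.93 and 7.58 FPKM in wild type and at 87.7, 82.1 and 33.9 FPKM in heterozygotes (log2 fold change 3.16, SE 0.37, limma adjusted p = 0.231). The output factor Dbp was at 2.36 FPKM in wild type and 28.3 FPKM in heterozygotes (log2 fold change 2.96, SE 0.59), and Nr1d2 at 7.56 and 21.7 FPKM (log2 fold change 1.35, SE 0.36). Cry1, a repressor of the clock (chromosome 10, 85131700 to 85185064), was at 10.1 ± 0.938 FPKM in wild type and 2.81 ± 0.993 FPKM in heterozygotes (log2 fold change -1.58, SE 0.19). Over all genes 0 of the 19 passed. Adjusted over the list alone, 3 passed as higher (Nr1d1, Dbp and Nr1d2) and 1 as lower (Cry1). Members went both ways, and the list as a whole was not called (mean log2 fold change 0.26, camera adjusted p = 0.909). A form of fry that ignores the direction of each gene did not call it either (fry adjusted p = 0.113). Without heterozygote replicate 3, whose Nr1d1 and Dbp were the lowest of its group, Nr1d1 passed over all genes (log2 fold change 3.59, limma adjusted p = 0.0385).

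**Figure D3:**
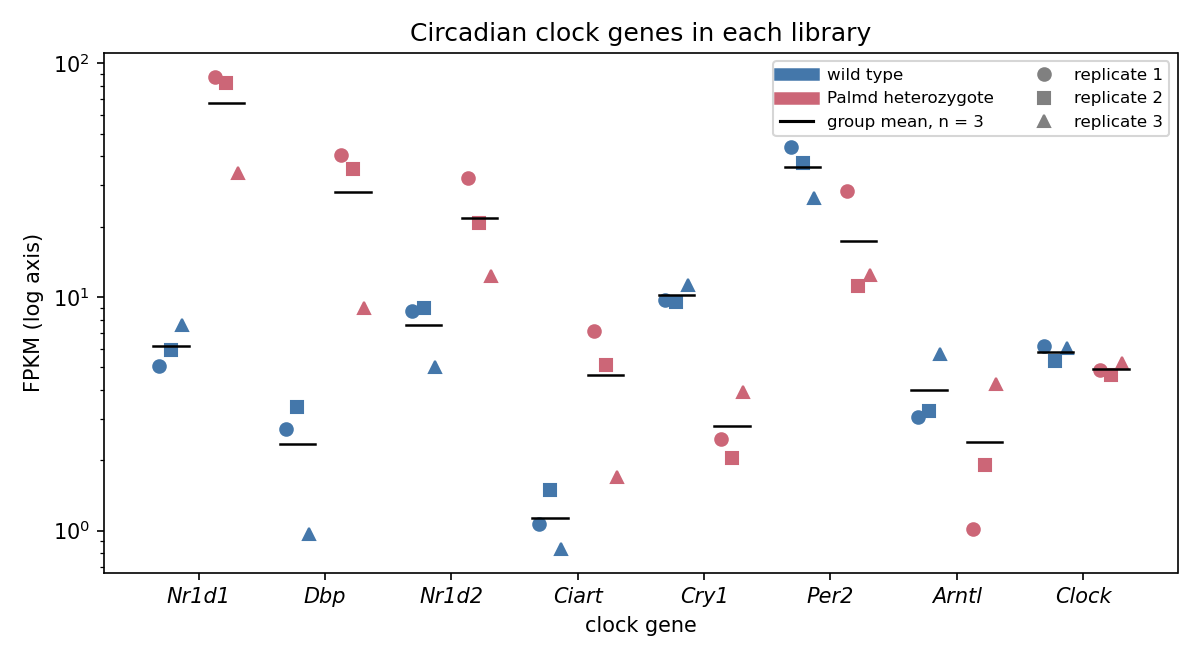
FPKM on a log axis of 8 clock genes in each library, with lines at the means of 3 libraries. The heterozygote values of Nr1d1 (33.9 to 87.7 FPKM) lie above all wild-type values (5.07 to 7.58 FPKM), and those of Cry1 lie below.

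Of the 47 lists tested with camera, 13 were called, 3 higher and 10 lower in heterozygotes, at the preset correlation. With an estimated correlation 0 lists were called, and with fry 0. The fibrillar collagens rose as a list, with 8 of 9 members higher (mean log2 fold change 0.49, camera adjusted p = 0.00201, and adjusted p = 0.800 with an estimated correlation). Col1a1 was at 601 FPKM in wild type and 1122 FPKM in heterozygotes (log2 fold change 0.89, SE 0.26), and Col3a1 at 301.6 and 564 FPKM (log2 fold change 0.88, SE 0.24). Col1a2 and Col14a1 had log2 fold changes of 0.59 and 0.37, Col5a1 one of 0.42, and Col12a1 went the other way at -0.33. The groups did not overlap for 4 members that were higher and 1 that was lower. Over all genes 0 members passed, and adjusted over the list alone 0.

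Elastic fibre genes moved both ways and were not called as a list (mean log2 fold change 0.08, camera adjusted p = 0.536). Adjusted over the list alone, 2 of 18 passed as higher and 1 as lower. The fibrillin Fbn1 was at 23.8 FPKM in wild type and 39.3 FPKM in heterozygotes (log2 fold change 0.69, SE 0.14). Mfap2 was the other higher member, and the lower member was Ltbp2, a latent TGF-beta binding protein, at 22.5 and 15.5 FPKM (log2 fold change -0.51, SE 0.11). Loxl2, Efemp1 and Loxl1 had log2 fold changes of 0.50, -0.19 and 0.27, where Loxl1 was at 0.50 without heterozygote replicate 2. Among 19 matrix proteases and inhibitors, Mmp9 passed over the list alone, Adamts5, Mmp14 and Mmp2 had log2 fold changes of 0.43, 0.60 and 0.51, and the inhibitor Timp3 and Mmp3 had ones of -0.64 and -0.54, which were -0.38 and -0.33 without heterozygote replicate 2. That list was not called (camera adjusted p = 0.895), nor were the basement membrane genes (0.563), of which Lama2 had a log2 fold change of 0.37. The proteoglycans and matricellular proteins (mean log2 fold change -0.05, camera adjusted p = 0.696) and the collagen processing genes (mean -0.10, camera adjusted p = 0.448) were not called either. In these Tnxb had a log2 fold change of 0.40, Thbs1 of -0.96, and the collagen prolyl hydroxylases P4ha1 and P4ha2 of -0.94 and -0.51. With heterozygote replicate 2 left out, Thbs1, P4ha1 and P4ha2 were at -0.35, -0.51 and -0.15. Heterozygote replicate 2 had the lowest level of these matrix lists apart from the collagens. Without it the elastic fibre, proteoglycan and collagen processing genes were called as higher, with means of 0.33, 0.22 and 0.16 and camera adjusted p of 1.05e-05, 0.00660 and 0.0272, and the basement membrane genes with a mean of 0.17 and camera adjusted p of 0.0284. With an estimated correlation the adjusted p was 0.650 for each of these lists. None of the first 2 or the basement membrane genes (mean 0.05) was called with another library left out. The elastic fibre mean was 0.05, -0.03 and -0.04 without wild type replicate 3, heterozygote replicate 1 and heterozygote replicate 3, and the basement membrane mean 0.01, -0.04 and 0.02. The proteoglycan mean was -0.13, -0.20 and -0.17 without the same libraries. Without wild type replicate 1 it turned to 0.01 and the basement membrane mean was 0.09. The proteoglycans were called as lower with the white adipocyte marker level as a covariate (mean -0.16, camera adjusted p = 0.0346, and adjusted p = 0.642 with an estimated correlation). The direction of the collagen processing genes turned with the library left out. They were called as lower without heterozygote replicate 3 (mean -0.24, camera adjusted p = 0.0345, and adjusted p = 0.929 with an estimated correlation), and had a mean of -0.21 without heterozygote replicate 1, with no call.

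The contractile smooth muscle genes showed no call in the comparison of all libraries. Their mean log2 fold change was -0.06 over 18 genes (camera adjusted p = 0.438), and no member had groups that did not overlap. The actin Acta2 was at 7117 FPKM in wild type and 6694 FPKM in heterozygotes (log2 fold change -0.17, SE 0.45). The 6 members with the smallest p, Tagln, Myocd, Cald1, Myl9, Myh11 and Tpm1, had log2 fold changes of -0.20, -0.30, -0.17, 0.22, 0.20 and -0.15, with SE of 0.21 to 0.44. Leaving out heterozygote replicate 2 gave -0.0043, 0.13, 0.07, 0.55, 0.48 and 0.13. Acta2, added after its value was seen, was at 8012, 3701 and 8367 FPKM in heterozygote replicates 1 to 3, and its log2 fold change was 0.22 without heterozygote replicate 2. The direction depended on the library left out and on the covariate. The list was called as higher without heterozygote replicate 2 (mean 0.23, 17 of 18 genes higher, camera adjusted p = 0.0193, and adjusted p = 0.736 with an estimated correlation). It was called as lower without wild type replicate 3 (mean -0.20, camera adjusted p = 0.0305, and adjusted p = 0.965 with an estimated correlation) and with the white adipocyte marker level as a covariate (mean -0.19, camera adjusted p = 0.00123, and adjusted p = 0.511 with an estimated correlation). It was not called without wild type replicate 1 (mean 0.06), heterozygote replicate 1 (-0.22) or heterozygote replicate 3 (-0.18). The SRF and actin cytoskeleton list fell at the preset correlation, with 18 of 20 genes lower (mean -0.18, camera adjusted p = 0.0244, and adjusted p = 0.944 with an estimated correlation). Adjusted over the list alone 0 passed. Pdlim5, Wdr1, Actg1 and Tpm4 had log2 fold changes of -0.59, -0.34, -0.37 and -0.39, and of -0.27, -0.13, -0.14 and -0.10 without heterozygote replicate 2. The call of the SRF list was lost without heterozygote replicate 2, where the mean was 0.08, without wild type replicate 1 (-0.10) and without wild type replicate 2 (camera adjusted p = 0.0584). The mean was -0.33 without heterozygote replicate 1 and -0.28 without heterozygote replicate 3.

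The osteochondrogenic genes, which mark a bone- or cartilage-like program, were not called (11 tested, mean log2 fold change -0.21, camera adjusted p = 0.510). Acan was at 4.12 ± 1.61 FPKM in wild type and 1.84 ± 0.802 FPKM in heterozygotes, and Spp1 at 0.768 and 1.28 FPKM. Pth1r was at 5.52 ± 0.722 and 11.0 ± 7.24 FPKM, with 19.4 FPKM in heterozygote replicate 2, without which its log2 fold change was 0.27 instead of 0.73. Cytl1, Bmp6 and Chad had log2 fold changes of -1.09, -0.65 and -0.53 with SE of 0.82, 0.62 and 0.52, and each was lowest in heterozygote replicate 2. Without that library they were at -0.07, 0.11 and 0.09, and the list mean was 0.11, with no call (camera adjusted p = 0.242). It was -0.35 and -0.38 without heterozygote replicates 1 and 3. The cartilage markers were not called (4 tested, mean -0.54, camera adjusted p = 0.0879). They were called as lower without wild type replicate 3 (mean -0.66) or heterozygote replicate 3 (mean -0.75), and not with an estimated correlation. Leaving out heterozygote replicate 2 gave a mean of -0.15 and a median of -0.03, with no call (camera adjusted p = 0.442). The 10 mineralization inhibitors fell as a list at the preset correlation, with all 10 lower (mean -0.33, camera adjusted p = 0.00810, and adjusted p = 0.936 with an estimated correlation). Smad6 passed over the list alone, while Ahsg, Mgp and Nog had log2 fold changes of -0.48, -0.56 and -0.31 with overlapping groups, and of -0.10, -0.10 and -0.05 without heterozygote replicate 2. With heterozygote replicate 2 left out the mean was -0.10 and the call was lost (camera adjusted p = 0.271), and without heterozygote replicate 1 the mean was -0.50. The TGF-beta and BMP targets fell in the same way (19 genes, 15 lower, mean -0.28, camera adjusted p = 0.00201, and adjusted p = 0.944 with an estimated correlation). Besides Ltbp2, the feedback regulators Skil and Smad7 had log2 fold changes of -0.80 and -0.97 and Id2 one of -0.39, and Smad7 was at -0.64 without heterozygote replicate 2. With heterozygote replicate 2 left out the mean was -0.03 and the call was lost (camera adjusted p = 0.333), and without heterozygote replicate 1 the mean was -0.44.

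The lists of cellular stress fell at the preset correlation. Of 17 endoplasmic reticulum stress genes 16 were lower (mean log2 fold change -0.67, camera adjusted p = 3.06e-11, and adjusted p = 0.800 with an estimated correlation), and for 9 of them the groups did not overlap. Adjusted over the list alone 3 passed: the cochaperone Dnajb9 (25.5 ± 2.80 and 16.8 ± 1.62 FPKM in wild type and heterozygotes), the transcription factor Xbp1 (83.5 ± 17.5 and 49.3 ± 5.83 FPKM) and Sdf2l1 (log2 fold change -1.46, SE 0.38). Manf had a log2 fold change of -1.14. The heat shock genes had a mean of -0.79 with 11 of 13 lower (camera adjusted p = 1.30e-06, and adjusted p = 0.800 with an estimated correlation). Hspb1 was at 535 and 187 FPKM, Hsp90aa1 at 158 and 80.7 FPKM and Hspa8 at 555 and 301.2 FPKM, and these 3 passed over the list alone, while Dnaja1 (-0.84) did not. Immediate early genes, which respond within minutes to handling and other stimuli, had a mean of -0.59 with 20 of 23 lower (camera adjusted p = 5.41e-08, and adjusted p = 0.800 with an estimated correlation). Nr4a2, Junb, Ier2 and Egr2 had log2 fold changes of -1.64, -1.25, -0.88 and -0.47 and passed over the list alone. The level of the immediate early list was lower in wild type replicate 3 than in heterozygote replicate 1. That of the heat shock list was about the same in wild type replicate 1 (6.55927) and heterozygote replicate 3 (6.55975), so its groups also overlapped. Heterozygote replicate 2 was the lowest library in all 3 lists. Without it the means were -0.50, -0.45 and -0.31, the calls at the preset correlation held, and no list was called with an estimated correlation.

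**Figure D4:**
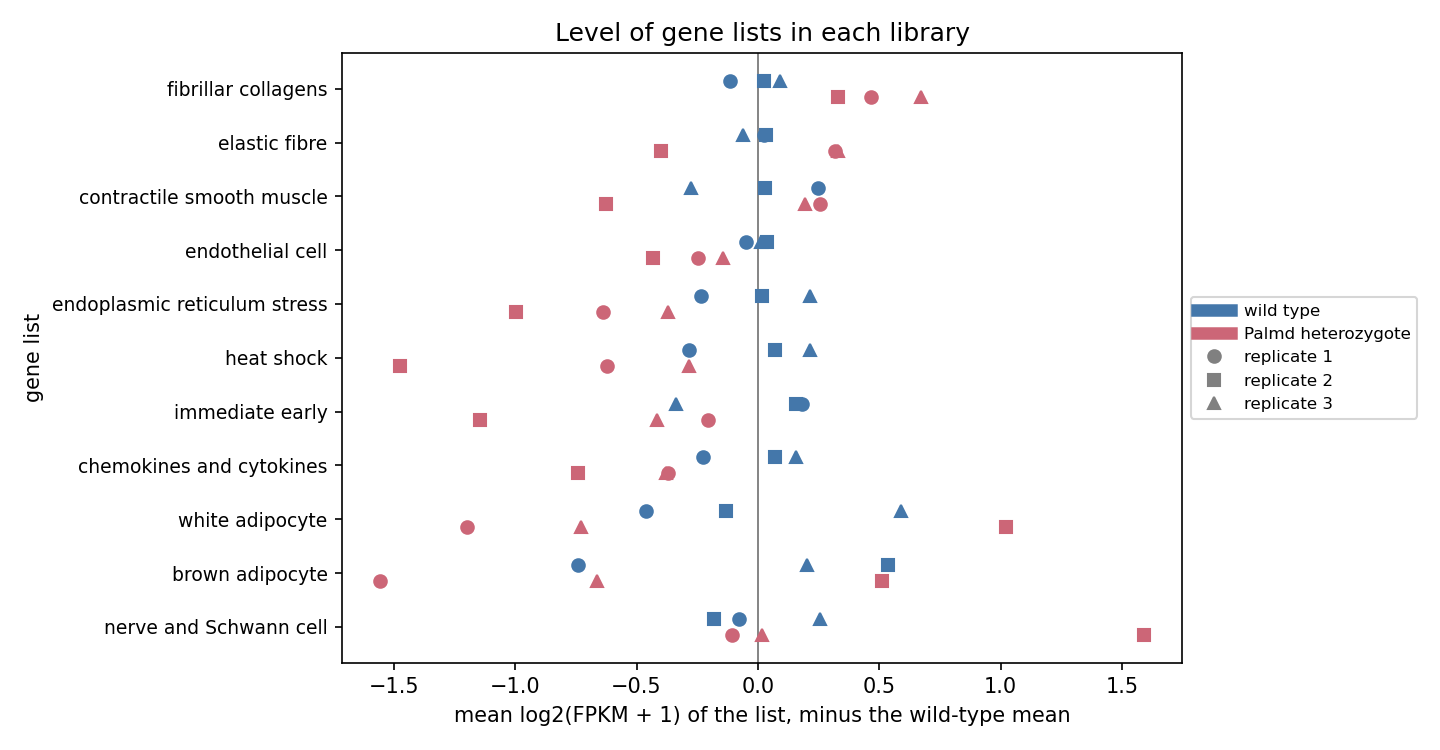
Mean log2(FPKM + 1) of 11 gene lists in each library, minus the mean of the wild-type libraries (horizontal axis). The heterozygotes lie above wild type for the fibrillar collagens and below it for the endoplasmic reticulum stress genes, and heterozygote replicate 2 lies apart from the others in most lists.

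Endothelial markers fell as a list, with 13 of 16 lower (mean -0.27, camera adjusted p = 0.00839, and adjusted p = 0.800 with an estimated correlation). The correlation estimated for this list was 5.3e-04, below the preset 0.01, yet the unadjusted camera p rose from 0.00143 to 0.0271. A higher correlation between its genes is thus not the reason that this call was lost. Egfl7 was at 35.3 ± 2.57 and 24.6 ± 6.31 FPKM, Flt1, Emcn and Esam had log2 fold changes of -0.41, -0.18 and -0.37, and 0 passed over all genes or adjusted over the list alone. Leaving out heterozygote replicate 2 moved Egfl7 from -0.53 to -0.33 and Esam to -0.08. The vascular tone genes were not called (camera adjusted p = 0.286). In them the endothelial nitric oxide synthase Nos3 had a log2 fold change of -1.09 (SE 0.47), which was -0.53 without heterozygote replicate 2, Ednra one of 0.30, Gucy1a3 of 0.42 and Adra1a of -0.54. Notch signalling was not called (mean -0.25, camera adjusted p = 0.0745). It was called as lower without wild type replicate 3 (mean -0.32) or heterozygote replicate 1 (mean -0.34), and not with an estimated correlation. Leaving out heterozygote replicate 2 gave -0.15 (camera adjusted p = 0.108). Its ligand Dll1 was at 21.6 ± 6.59 and 8.06 ± 3.88 FPKM and Notch1 at 13.5 ± 1.32 and 8.86 ± 3.04 FPKM, with Hes1 and Notch3 at log2 fold changes of -0.47 and 0.21. Notch1 moved from -0.60 to -0.38 and Hes1 to -0.29 without heterozygote replicate 2. The Wnt targets were not called (mean 0.17, camera adjusted p = 0.162), and Tcf7 had a log2 fold change of 0.75. When heterozygote replicate 2 was left out, all 12 Wnt targets were higher and the list was called (mean 0.36, camera adjusted p = 2.34e-04, and adjusted p = 0.650 with an estimated correlation). The mean was 0.07 and 0.08 without heterozygote replicates 1 and 3.

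Chemokines and cytokines fell as a list (12 of 15 lower, mean -0.50, camera adjusted p = 3.21e-05, and adjusted p = 0.800 with an estimated correlation). Ccl7 was at 3.41 ± 1.57 and 1.03 ± 0.238 FPKM, Cxcl13 at 4.03 ± 1.19 and 1.52 ± 0.840 FPKM, Ccl9 at 14.5 ± 3.28 and 8.06 ± 1.88 FPKM and Ccl2 at 2.27 ± 0.956 and 0.901 ± 0.204 FPKM. Each had groups that did not overlap, and 0 passed over the list alone. Neutrophil and mast cell markers rose at the preset correlation (6 of 7 higher, mean 0.35, camera adjusted p = 0.0228, and adjusted p = 0.800 with an estimated correlation). The lower member was the neutrophil marker Csf3r (log2 fold change -0.30), named after its value was seen. Besides Mmp9, the mast cell proteases Cma1, Mcpt4 and Cpa3 had log2 fold changes of 0.56, 0.54 and 0.46 with overlapping groups, and of 0.34, 0.36 and 0.29 without heterozygote replicate 2. This call was lost without heterozygote replicate 2 (mean 0.21), without wild type replicate 2 (0.26), in limma voom (0.27) and with array quality weights (0.39), and with no filter on low values the mean was -0.02. Macrophage markers (camera adjusted p = 0.737), interferon-stimulated genes (0.248), complement (0.583), MHC class II genes (0.134) and lymphocyte markers (0.164) were not called. Without wild type replicate 1 the complement (mean -0.16) and interferon-stimulated genes (-0.16) were called as lower, and without heterozygote replicate 2 the MHC class II genes (-0.23). With all libraries their means were -0.05, -0.07 and -0.14. The complement mean turned to 0.03 without wild type replicate 3 and the MHC class II mean to 0.0060 without heterozygote replicate 1. The complement mean was -0.12 without heterozygote replicate 3 and -0.01 to -0.02 without any of the other 3 libraries. That of the interferon-stimulated genes was -0.13 without heterozygote replicate 2 and -0.02 to -0.04 without any of the other 4. Lymphocyte markers (mean 0.27) were called as higher without wild type replicate 2 (0.38), heterozygote replicate 1 (0.40) or heterozygote replicate 3 (0.40), while the mean was 0.0065 without heterozygote replicate 2 (camera adjusted p = 0.718, with the test in the other direction). None of these was called with an estimated correlation. The macrophage receptor Csf1r had a log2 fold change of 0.37 and Cd14 one of -0.45.

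Markers of fat differed widely between libraries of each group. The mean log2 level of the white adipocyte markers was 5.98, 6.31 and 7.03 in wild type replicates 1 to 3 and 5.24, 7.46 and 5.71 in heterozygote replicates 1 to 3. Ucp1, the uncoupling protein of brown fat, was at 117, 682 and 489 FPKM in wild type and 34.9, 790.3 and 153 FPKM in heterozygotes. The white adipocyte list was not called (mean -0.30, camera adjusted p = 0.112), and was called as lower without heterozygote replicate 2 (mean -0.96) or wild type replicate 1 (-0.53), though not with an estimated correlation. It turned to 0.15 without heterozygote replicate 1, and was -0.0059 and -0.09 without wild type replicate 3 and heterozygote replicate 3. The brown adipocyte list (13 genes, mean -0.57, camera adjusted p = 0.0365, and adjusted p = 0.944 with an estimated correlation) and fatty acid oxidation (18 genes, mean -0.37, camera adjusted p = 0.0342, and adjusted p = 0.944 with an estimated correlation) fell at the preset correlation. The brown adipocyte genes Dio2, Fabp3, Slc27a2 and Cidea had log2 fold changes of -0.77, -1.32, -0.79 and -0.85, where Slc27a2 and Cidea were at -1.22 and -1.75 without heterozygote replicate 2. Both calls were lost on leaving out any of wild type replicates 2 and 3 and heterozygote replicates 1 and 3, and with scaling by the median of ratios or the upper quartile. The means of the brown adipocyte and oxidation lists were -0.08 and 0.01 without heterozygote replicate 1, -0.30 and -0.26 without wild type replicate 2, -0.47 and -0.17 without wild type replicate 3, -0.52 and -0.21 without heterozygote replicate 3, -1.11 and -0.89 without heterozygote replicate 2, and -0.94 and -0.66 without wild type replicate 1. Nerve and Schwann cell markers were called as higher (12 genes, mean 0.50, camera adjusted p = 0.0451, and adjusted p = 0.944 with an estimated correlation), with a level of 4.10 in heterozygote replicate 2 and 2.33 to 2.76 elsewhere. Without that library the mean was -0.04 and the call was lost. The call was also lost without wild type replicate 1 (mean 0.46) or 2 (0.41), and without heterozygote replicate 1 the mean was 0.81. Heterozygote replicate 2 also had the largest share of reads on mitochondrially encoded genes, 8.67% against 3.65% to 6.22%.

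Fibroblast (camera adjusted p = 0.815), pericyte (0.574), mesothelial (0.336), erythroid (0.361) and skeletal muscle markers (0.933) were not called. The direction of the erythroid markers (mean -0.30) turned with the library left out. They were called as lower without wild type replicate 3 (mean -0.78), and not with an estimated correlation. Without wild type replicate 2 the mean was 0.15, with all 5 members higher and no call, and it was -0.71, -0.10 and -0.07 without heterozygote replicates 1, 2 and 3. The fibroblast markers (mean 0.02) had a mean of 0.19 without heterozygote replicate 2 and were called (camera adjusted p = 0.0175, and adjusted p = 0.713 with an estimated correlation). Their mean was -0.05, -0.02 and -0.09 without wild type replicate 1, heterozygote replicate 1 and heterozygote replicate 3, and 0.05 and 0.07 without wild type replicates 2 and 3, with no call. Oesophageal and epithelial markers were at or below 0.329 FPKM in every library. Cardiac muscle and thymus or lymph node markers had too few tested members for a list test, and their highest genes were Actc1 (12.4 ± 5.83 and 11.5 ± 5.32 FPKM) and Ccl21a (32.1 ± 3.32 and 52.8 ± 14.3 FPKM).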

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

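The array quality weights, the covariate, the header block, trimmed-mean scaling, the other pseudocounts and the minimum of 5 FPKM were chosen after the data were seen. Apart from the weights and the covariate, the count of genes past the threshold was 0 in every setting with all 6 libraries, including an adjusted p of 0.1 and a test against a fold of 1.5, and 0 to 1 when each library was left out in turn. The gene was Gm17720 without wild type replicate 1, Trbd1 without wild type replicate 2, Zbtb16 without heterozygote replicate 1 and Nr1d1 without heterozygote replicate 3. Array quality weights, which were estimated from the same values, called 232 genes (150 higher, 82 lower). Heterozygote replicate 3 had a weight of 3.59 and wild type replicate 2 one of 3.11. Heterozygote replicate 2 had a weight of 0.170, and the other libraries had 0.668 to 1.04. The calls with weights thus rest mostly on heterozygote replicate 3 and wild type replicate 2. The adipocyte covariate called 63 genes (30 higher, 33 lower), and 34 genes were called by both. With the covariate the smallest limma adjusted p was 0.0497, so all 63 lay just under the threshold of 0.05. All 24 named genes passed with the weights and 14 with the covariate. Over all settings, 452 of 491 values of named genes stayed on the same side of the threshold and 39 newly passed it, and of 259 values of the called lists 215 kept the call, 39 lost it and 5 reversed. Palmd was below wild type in all 20 settings (log2 fold change -0.46 to -0.08, adjusted p 0.208 to 1.00). The number of lists called ranged from 9 (without wild type replicate 2) to 23 (without heterozygote replicate 2), against 13. With an estimated correlation it was 0, and with fry, run on the 6 libraries without other changes, 0. Of the 19 lists called with the weights 8 were among the 13, and of the 18 called with the covariate 11. Fatty acid and triglyceride synthesis was called as higher with the covariate (mean 0.30) and as lower with the weights (-0.55). The endoplasmic reticulum stress, heat shock, immediate early, chemokine, collagen and endothelial lists were called in all 20 settings at the preset correlation. The settings reuse the same libraries and the same preset correlation, so these repeats are not independent support. Means that reversed (log2 fold change) were -0.021 for neutrophil and mast cell markers with no filter, 0.0066 for fatty acid oxidation without heterozygote replicate 1, 0.077 for the SRF list and -0.044 for nerve markers without heterozygote replicate 2, and 0.031 for the SRF list with the weights. Over the libraries left out in turn these means ranged from -0.33 to 0.077 for the SRF list, from -0.89 to 0.0066 for fatty acid oxidation and from -0.044 to 0.81 for nerve markers. The cause was not tested, beyond the fewer samples used where a library was left out. A replicate block by title number gave 0 genes and 14 lists, and by header number 0 genes and 13 lists. Libraries with title number 1 deviated together (r = 0.51), but those with title numbers 2 and 3 did not (r = -0.09 and -0.34). Libraries with the same header number did not either (r = -0.47, 0.14 and -0.54). The numbers were therefore not taken to pair samples, though these values do not show that the samples were unpaired. The planned count models with other scaling factors and the minimum in CPM were not run because the files hold FPKM. At these depths 1 read on a 2 kb gene is at most 0.0289 FPKM, below the minimum of 1.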

Other observations

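All tests given here except the planned tests of gene lists and the libraries left out in turn were chosen after the results were seen.

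Glycolysis genes were not called in the planned comparison of all 6 libraries (mean log2 fold change 0.14, camera adjusted p = 0.108). They were called as higher without wild type replicate 3 (mean 0.21), heterozygote replicate 1 (0.39) or heterozygote replicate 3 (0.24) and with the adipocyte covariate (0.29), and not without wild type replicate 1 (0.05). With an estimated correlation they were called in none of these settings. Pfkm, Pgam2, Eno3 and Pfkp, all with groups that did not overlap, had log2 fold changes of 0.45, 0.45, 0.52 and 0.23. Oxidative phosphorylation (camera adjusted p = 0.329), fatty acid and triglyceride synthesis (0.438), cholesterol synthesis (0.567), mitochondrially encoded genes (0.977), ribosomal proteins (0.565), cell cycle (0.709), autophagy and lysosome (0.852), and antioxidant genes (0.343) were not called in that comparison. Among senescence and p53 targets (camera adjusted p = 0.164) the cyclin-dependent kinase inhibitor Cdkn1a was at 91.7 ± 19.1 FPKM in wild type and 40.3 ± 16.8 FPKM in heterozygotes. Without heterozygote replicate 2, which had the highest level of the lists of energy and lipid metabolism, oxidative phosphorylation (mean -0.52, and -0.32 without wild type replicate 1, also called), fatty acid and triglyceride synthesis (-1.10), cholesterol synthesis (-0.50), glycolysis (-0.21), mitochondrially encoded genes (-0.34) and the white adipocyte markers (-0.96) were called as lower and ribosomal proteins (0.12) as higher. None of these was called with an estimated correlation. The directions turned with the library left out. Over the other 5 libraries left out in turn, the mean of oxidative phosphorylation ran from -0.32 (wild type replicate 1) to 0.22 (heterozygote replicate 1), that of fatty acid and triglyceride synthesis from -0.33 (wild type replicate 2) to 0.58 (heterozygote replicate 1) and that of cholesterol synthesis from -0.21 to 0.22 (the same libraries). The mitochondrially encoded genes ran from -0.04 (wild type replicate 1) to 0.40 (heterozygote replicate 1), the ribosomal proteins from -0.04 (heterozygote replicate 3) to 0.09 (wild type replicate 2) and the white adipocyte markers from -0.53 (wild type replicate 1) to 0.15 (heterozygote replicate 1). Of these values those of oxidative phosphorylation and the white adipocyte markers without wild type replicate 1 were called. The mean, the median and the direction of the test differed in sign for the basement membrane, cell cycle, macrophage, matrix protease, skeletal muscle and mitochondrially encoded lists.

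The clock genes that peak in the light phase or at dusk, such as Dbp, were higher relative to those that peak at night or at dawn, such as Cry1, by 1.40 on the log2 scale (SE 0.57) over all 19 clock genes, each given a phase after its values were seen. A narrower choice of 14 of them, which left out Per2 and Per1, gave 2.04 (SE 0.67). Per2, named after its values were seen, moved opposite to Dbp. It was at 35.9 FPKM in wild type and 17.3 FPKM in heterozygotes (log2 fold change -1.10, SE 0.37), with overlapping groups. The 6 genes whose groups did not overlap, taken by that outcome, differed by 3.08. With the adipocyte marker level as a covariate the difference over all 19 was 1.40 (SE 0.68), just above 2 of its errors. Without heterozygote replicate 2, and with no covariate, it was 1.21 (SE 0.70), under 2 of its errors. With so few libraries these values do not decide for or against different shares of fat. Collection at another time of day would give such a difference, but the labels hold no time of collection, and an effect of genotype on the clock may give the same pattern. Time of collection and genotype cannot be told apart here.

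The fibrillar collagens were higher by 0.49 (SE 0.12) in heterozygotes. A larger share of fibroblasts would raise the other fibroblast markers with them, but the collagen level minus the level of those markers also differed between the groups, by 0.50 (SE 0.09). Those markers were lowest in heterozygote replicate 2. Without that library they were higher in heterozygotes by 0.16 (SE 0.12), and the collagens minus the markers differed by 0.41 (SE 0.04). A larger share of cells with these markers thus does not account for all of the collagen rise, but may account for a part. Fibroblasts that make more collagen need not carry more of these markers. The comparison therefore cannot decide on a change in the kind or state of the fibroblasts. A smaller share of fat does not account for all of the collagen rise either, since the difference with the adipocyte marker level as a covariate was 0.48 (SE 0.13). Higher collagen transcript levels in the heterozygotes may be biological, as a hypothesis. Genotype itself, the time of collection, which is not in the labels, and other differences between the animals stay open, as untested.

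The 52 genes of the endoplasmic reticulum stress, heat shock and immediate early lists were lower by 0.67 (SE 0.26). Heterozygote replicate 2 alone does not account for all of this pooled difference, since without it the mean was -0.42 (SE 0.07). Pooling narrows that error, because the lists ran in opposite directions over wild type replicates 1 to 3. The immediate early level was 4.99, 4.96 and 4.47 there, and the heat shock level 6.56, 6.91 and 7.06. Each of these 2 lists overlapped between the groups without heterozygote replicate 2 as well, so for each alone the question stays undecided. A lower temperature of the animal or tissue at collection may be a source of the lower stress levels. The cold-inducible genes Cirbp and Rbm3, chosen after their values were seen, had a mean log2 fold change of 0.66 (SE 0.15). Body temperature follows the time of day, neither is in the labels, and genotype differs with the same libraries, so these cannot be told apart.

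The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest of the others 0. As any split gives at least 0, that all 10 did so says nothing. At an unadjusted p under 0.05 the real split gave 820 genes, and 2 of the 10 splits gave as many or more. The highest other was 2314, for wild type replicate 1 with heterozygote replicates 1 and 3 against the rest. That split points to a structure of the samples, as it parts the libraries with the lowest white adipocyte markers (5.24 to 5.98) from those with the highest (6.31 to 7.46). The real split called 13 lists at the preset correlation and the others 16 to 29, and all 10 splits called as many or more. The number of lists called at the preset correlation is thus no evidence of a difference between the genotypes.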
